A study of Pistia stratiotes with 8 samples.

How the data were processed

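Messenger RNA was sequenced from leaves and roots of Pistia stratiotes, a free-floating freshwater plant of the arum family. Per the labels' protocols, 1 mature plant was placed in each 500 ml flask with 200 ml of SH medium, and the plants were grown for 10 days. Young plants with 3 to 4 leaves were then sampled. The leaf samples were the largest emerged leaves and the root samples were roots without their tips and side roots. The tissue pooled from a flask was 1 biological replicate, with 4 per tissue. Poly(A) RNA was turned into cDNA with random hexamers, and the libraries were read as 150 bp pairs. No step that marks the strand is described in the labels' protocols.

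The deposited table holds 1 row for each of 16504 transcript models and 1 column for each of the 8 libraries, and no column went unused. The submitters' processing notes name Salmon and DESeq2, without their role, order or version. The aligner settings, the transcript set and the genome build are not given in the sources used here. Although the table is described as counts, the deposited values are a normalized signal (normalized counts), because the authors had already scaled them. No value above 0 was a whole number (0% of them), and the column-wise medians of the ratio to each model's geometric mean lay between 1.00 and 1.02. Such medians are what median-of-ratios scaling leaves. In each column the lowest values above 0 formed 1 band, taken as the worth of a single read. The median of the band ran from 0.928 to 1.45 normalized counts. Its 5th to 95th percentiles spanned 5.2% to 10.2% of the median in 7 libraries and 25.5% in root library 1. The worth of a read was thus not exact, and whole reads were not recovered. The reason for the width of the band was not tested. Column total divided by the median worth of a read gave an estimated depth of 5814000 to 6209000 reads per library. A read-count test planned before the data were examined was therefore replaced by a test on the log scale. Low values carry counting error that the scaled table does not state, and no counting interval is given.

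Leaf columns are numbered 1 to 4, whereas the leaf labels carry the numbers 1, 3, 4 and 5, so a leaf column was assigned to its tissue but not to a particular label. Library numbers below are those of the table. The deviations of same-numbered leaf and root libraries from their tissue means correlated between -0.02 and 0.03. Since equal numbers need not mark the same flask, this cannot show whether leaf and root samples were paired. Leaf and root were treated as unpaired.

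Models with at least 10 normalized counts in at least 4 libraries (3 when a library was left out) were tested, 13688 in all. Values were taken as log2(normalized count + 1), a scale that understates the change of weakly expressed models. Leaf was compared with root by limma 3.58.1 in R 4.3.3 with a trended prior variance, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit used all 8 libraries with tissue as the only term. A second limma test (treat) asked whether a difference exceeded 2-fold. The test was run on simulated data made from the mean and spread of each model in this leaf against root comparison, with 50 models changed at each of 4 sizes and 13796 tested. It called 4% of the models changed by 0.5 on the log2 scale, 38% at 1, 86% at 2 and 94% at 3, and 9 of 13596 unchanged models. With so few changed models the adjustment is stricter than in the real comparison, so these shares are not its limit of detection. The simulated leaf and root libraries also shared a common spread per model and, for unchanged models, a common mean, unlike the real ones. Large spreads were capped, and noise was drawn independently for each model. The 9 calls among unchanged models are therefore no error rate of the real comparison. Counting noise was added to a spread that already held it, and only models above a minimum mean were changed. Values per library were compared by exact permutation of the 8 libraries, two-sided, over 70 arrangements, where the smallest possible p is 0.0286. Each library was also expressed with its column total set to 1000000 (CPM). Organ-restricted models had at least 1 CPM in all 4 libraries of one tissue and under 0.1 CPM in all 4 of the other. Since 0.1 CPM is below the worth of a single read, these models are listed at 0 throughout the other tissue. A model was counted as detected at 10 times the worth of a read in its library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these values.

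The table names models only by number, with no gene name, and no genome or annotation was used here. The 23 gene lists fixed before the data were examined could not be matched to the models, so no list was tested and no gene function is given. The rule for naming models, also fixed then, took 2 models per direction: those with the largest difference among models past the 2-fold test, with no overlap between tissues and a mean of at least 10 CPM in the higher tissue. The alternatives covered the scaling, the filter, the pseudocount, the variance model, a replicate block and leaving out each library.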

Results

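Leaf and root transcriptomes of Pistia stratiotes, a floating aquatic plant with a rosette of leaves above the water and roots hanging in it, were measured in 4 leaf and 4 root libraries. Each library came from the pooled tissue of 1 flask. The column totals of the normalized table were 7299221 to 8749656 normalized counts in leaf and 5458151 to 5809933 in root. The estimated depth was similar in the tissues, at 6020500 ± 162000 reads in leaf and 5919500 ± 69500 in root (SD, n = 4 each; exact permutation test, two-sided, p = 0.314). The study's design poses 1 comparison, leaf against root, and asks which transcripts differ between the organs. Models carry numbers and no gene names, so the organs are described by how many models differed, by how much, and by how each pool of transcripts was built up.

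Leaf and root were separate in every library. The first principal component of the log2 values held 84.4% of the variance and parted the tissues, with leaf scores of 104 to 113 and root scores of -112 to -102. Rank correlations across the tested models were 0.931 to 0.974 among the 6 pairs of leaf libraries and 0.973 to 0.985 among the 6 pairs of root libraries. Between a leaf and a root library they were 0.765 to 0.806. These are correlations across models, which are not independent replicates. The second component held 6.1% of the variance and spread the leaf libraries, from 60.4 in leaf library 1 to -53.7 in leaf library 4, whereas the root libraries lay between -10.8 and 5.82.

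**Figure D1:**
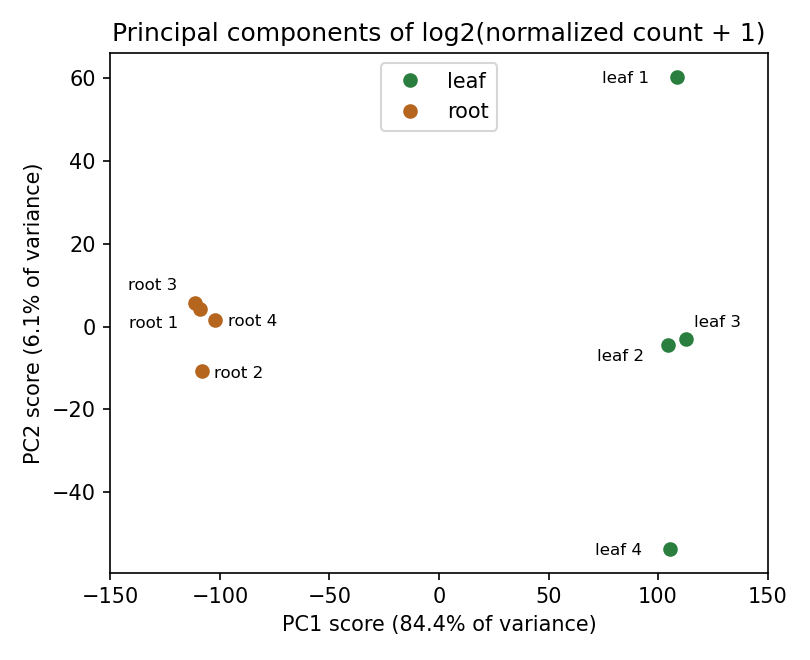
Scores of the 8 libraries on the first (x axis, 84.4% of variance) and second (y axis, 6.1%) principal components of log2(normalized count + 1); each point is 1 library, green for leaf and brown for root. The tissues lie apart on the first component, and leaf libraries 1 and 4 lie at opposite ends of the second.

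A large part of the tested transcriptome differed between the organs. Of 13688 tested models, 7063 (51.6%) were called, 3334 higher in leaf and 3729 higher in root (limma, Benjamini-Hochberg adjusted p under 0.05). Among called models on the deposited scale, differences in favour of root were the larger ones. The median size was 1.53 on the log2 scale among the models called higher in root and 1.15 among those higher in leaf. The upper quartiles were 3.05 and 1.82. A shift of the scale changes these sizes, which were not computed on another scale. A change above 2-fold was shown for 2456 models (17.9%), of which 904 were higher in leaf and 1552 higher in root (limma treat, adjusted p under 0.05). Above 4-fold the numbers were 322 in leaf and 847 in root. The median standard error of a log2 difference was 0.225, and 2591 of the 7063 called models had an estimate under 2-fold. The balance of directions depended on the scale. With each library scaled to its column total, which moved the median difference of all tested models from -0.05 to -0.53, 1822 models were higher in leaf and 6703 higher in root, so that leaf held 21.4% of the calls in place of 47.2%. Above 2-fold, scaling to column totals gave 561 models higher in leaf and 2170 higher in root. With quantile normalization leaf held 52.8%, with 3958 models higher in leaf and 3544 in root. The models above 2-fold stayed fewer in leaf (1012) than in root (1285) under quantile normalization.

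**Figure D2:**
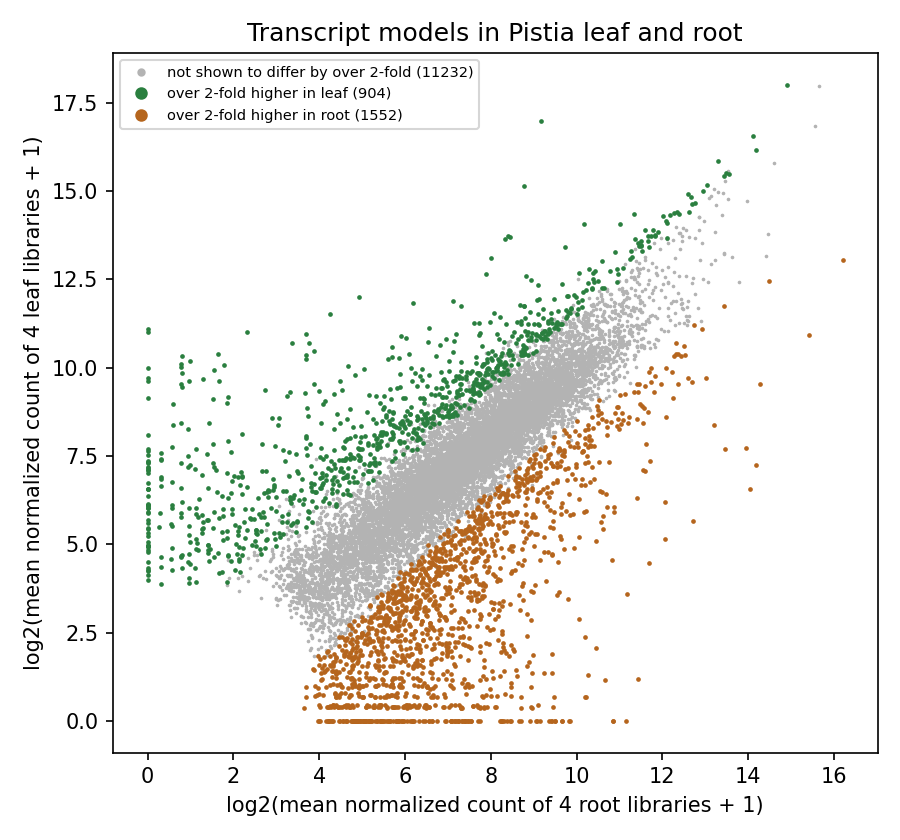
Mean of the 4 root libraries (x axis) against the mean of the 4 leaf libraries (y axis) for each tested transcript model, both as log2(mean normalized count + 1). Green points mark the 904 models shown to be over 2-fold higher in leaf, brown points the 1552 over 2-fold higher in root, and grey points the rest; the brown points reach down to 0 in leaf.

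On the deposited scale, the models over 2-fold higher in root had moderate levels in root, whereas those over 2-fold higher in leaf had high levels in leaf. Their median level was 112.7 normalized counts in root for the root-biased models, against 153.5 in root for all tested models. For the leaf-biased models it was 388.6 in leaf, against 149.2 in leaf for all tested models. Ranked by mean normalized count over all 8 libraries, the lowest quartile of tested models (3422 models, means up to 55.6) held 724 models over 2-fold higher in root and 212 over 2-fold higher in leaf. The highest quartile (means above 416.7) held 334 over 2-fold higher in leaf and 182 in root. This order in the highest quartile depended on the scale: it turned with column totals, at 160 in leaf and 296 in root, and came to 234 and 220 with quantile normalization. In the lowest quartile root kept the larger number under both, at 897 against 151 and 460 against 368. The excess of leaf-biased models in the highest quartile over the lowest also depended on the scale. The lowest and highest quartiles held 151 and 160 of them with column totals, and 368 and 234 with quantile normalization. A model at 0 in one tissue has a mean below its level in the other, so a quartile does not give its level in the tissue that expresses it. The leaf-biased models made up 28.0% ± 2.03 of a leaf library and 7.2% ± 0.66 of a root library. The root-biased models, although more numerous, made up 14.4% ± 0.47 of a root library and 1.3% ± 0.09 of a leaf library (SD, n = 4 each). These models were chosen for their difference between the same libraries, so the shares describe their weight in each pool and are no further test of the difference.

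The leaf pool was concentrated in few models. The 100 most abundant models of each library took 34.7% ± 3.67 of a leaf library and 19.8% ± 1.05 of a root library, a difference of 14.9 percentage points (SD, n = 4 each; exact permutation test, two-sided, p = 0.0286, the smallest possible). The single most abundant model took 3.58% ± 0.711 in leaf and 1.35% ± 0.325 in root, and the top 10 took 14.7% ± 2.26 and 6.49% ± 0.487 (exact p = 0.0286 for each). With 6 measures compared by exact tests in the same family, p = 0.0286 became 0.0343 after Benjamini-Hochberg adjustment. Leaf exceeded root in every library for all 3 measures. The lists of the 100 highest mean values in leaf and in root shared 53 models. Of the leaf list, 90 models were called higher in leaf, 52 of them over 2-fold, and 2 were called higher in root. Each list was picked by level in libraries that the test also used, so a lean towards its own tissue is partly built in. Of all 13688 tested models, 3334 were called higher in leaf and 3729 higher in root. On the scale of column totals the leaf list held 81 models higher in leaf and 7 higher in root, and with quantile normalization 65 and 7. Of the root list, 40 were called higher in root and 43 were called higher in leaf. This balance turned with the scale, to 52 higher in root and 35 higher in leaf with column totals and to 54 and 20 with quantile normalization.

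**Figure D3:**
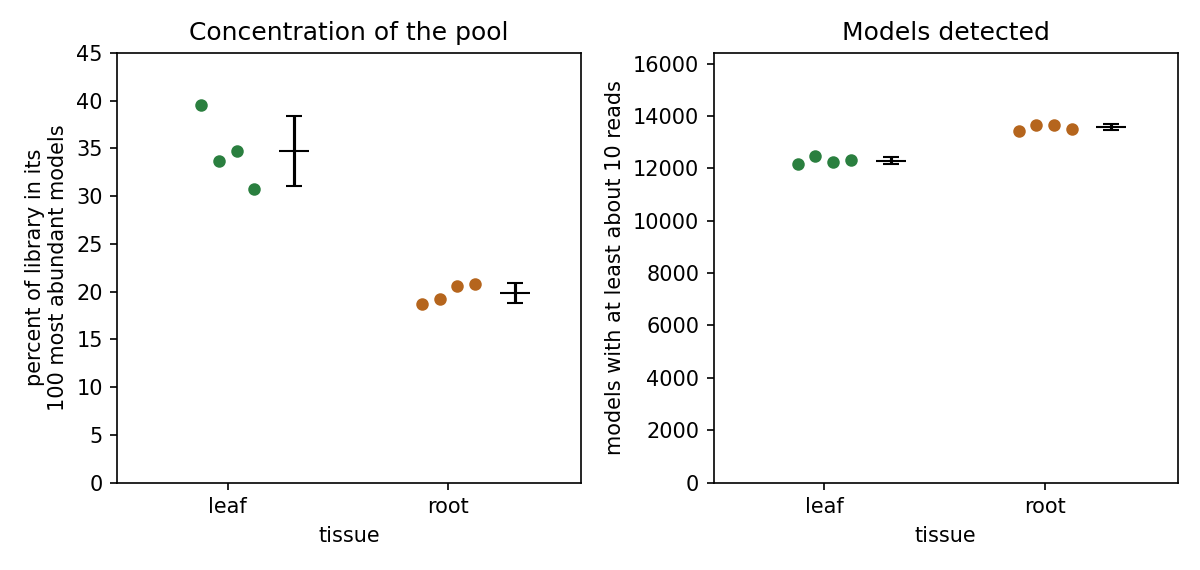
Left, percent of each library in its own 100 most abundant models; right, number of models with at least about 10 reads. Points are single libraries (4 leaf, 4 root) and bars are the mean ± SD; leaf libraries lie between 30.7% and 39.6% and root libraries between 18.7% and 20.8% on the left, and leaf lies below root on the right.

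More models were detected in root than in leaf. At about 10 reads or more, 13562 ± 117 models were detected in a root library and 12294 ± 125 in a leaf library, 1268 fewer (SD, n = 4 each; exact permutation test, two-sided, p = 0.0286). A leaf library listed 1476 ± 99.4 models at 0 and a root library 820 ± 128 (exact p = 0.0286), and 79 models were at 0 in all 8 libraries. Organ-restricted models followed the same direction. In root, 194 models had at least 1 CPM in every library while being listed at 0 in every leaf library. In leaf, 54 models had at least 1 CPM in every library while being listed at 0 in every root library. Their median level was 6.15 CPM for the root-restricted and 8.54 CPM for the leaf-restricted models, and the highest reached 405 and 273 CPM. With the limit in the other tissue raised to 0.5 CPM, the counts were 566 in root and 110 in leaf. These counts rest on the same low values and zeros as the models detected, so they are no separate evidence. A read was worth a mean of 1.31 normalized counts in leaf and 0.948 in root. A model at an equal normalized level thus falls to 0 more easily in leaf. On 1 common scale of normalized counts, 176 root-restricted and 56 leaf-restricted models were found, which does not remove this effect.

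The largest differences in each direction lay in such restricted models. Pis12031.t2 had 2068 ± 385 normalized counts in leaf and was listed at 0 in all 4 root libraries (SD, n = 4; limma adjusted p = 2.53e-10). Pis15720.t1 had 2190 ± 1002 in leaf, from 1528 in leaf library 4 to 3680 in leaf library 1, and was listed at 0 in root (limma adjusted p = 1.16e-09). In the other direction, Pis15862.t1 had 2272 ± 333 normalized counts in root and Pis01208.t1 had 1854 ± 271.8, and both were listed at 0 in all 4 leaf libraries (limma adjusted p = 2.53e-10 for each). No fold is given against a tissue listed at 0. Such a tissue adds no spread of its own, so the residual spread in these tests comes from the other tissue alone. The models were picked for their large differences in the same data, so their p-values are no further evidence.

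Leaf replicates differed from each other more than root replicates did. The median SD of a model's log2 value was 0.347 among the leaf libraries and 0.234 among the root libraries, a ratio of 1.48, and the leaf SD was the larger one for 71.1% of models. Between leaf libraries 1 and 4, 24.0% of tested models differed by more than 2-fold, against 10.5% to 15.5% for the other pairs of leaf libraries and 3.8% to 6.8% for pairs of root libraries. Without leaf library 1 the ratio was 1.17, and without root library 1, the library with the uneven worth of a read, it was 1.84. No test was made of this ratio, which compares the spread of 4 libraries with that of 4 others.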

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

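The tests on the spread of the leaf replicates and on the models detected were set out before their outcomes were seen, but after the patterns themselves had been seen in the same data.

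One value stood apart from its group on the scale of normalized counts. Pis15720.t1 had 3680 normalized counts in leaf library 1, while the other 3 leaf libraries had 1528 to 1863. Its gap to the nearest library was 0.844 of the range, above the 95% critical value of the Dixon test for 4 samples. The Dixon test was not run on the log2 scale used to compare the tissues, where a high value stands apart less. With 22 groups of values examined, chance alone flags about 1 in 20.

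All 4 leaf against root counts were set against other splits of the 8 libraries into 4 and 4. Of the 35 splits, 1, the real one, gave as many calls, for the models differing (7063), the models higher in leaf (3334), the models higher in root (3729) and those above 2-fold (2456). The highest value of any other split was 0 in each case by limma with adjusted p under 0.05, and the other 34 splits gave up to 1342 models at an unadjusted p under 0.05, against 7832 for the real split. Each other split mixes leaf and root, so that the organ difference enters its residual spread and lowers its count. Chance division is argued against for these 4 counts only by the rank of the real split, 1 of 35, which is the lowest share the splits can give; the zeros do not measure how many calls unrelated libraries would give.

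The wider spread among leaf than root replicates was weighed against several technical sources. Sampling noise of weakly expressed models is argued against, since the ratio of median SDs was 1.76 among the 757 models with a mean of at least 1000 normalized counts in each tissue. Root RNA carried into some leaf libraries is also argued against: root markers chosen without the library in question had a median level of at most 0.438% of their root level in any leaf library, and an upper quartile of at most 1.55%. With the scale recomputed by median of ratios, which a few abundant models hardly move, the ratio was 1.475. That value argues against a scale set by a few abundant models. Quantile normalization lowered the ratio from 1.48 to 1.27. It makes the distributions of all libraries alike, so it cannot test that source alone. A single leaf library stays open, since the ratio fell to 1.17 without leaf library 1. A difference between flasks, for instance in the age of the pooled leaves, may also contribute and was not tested, because the labels do not describe the flasks.

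The larger number of models detected in root could in part reflect reads taken up by the abundant leaf models. At 1 common threshold of 13.1 normalized counts, which on the deposited scale offsets those reads, root still had 811.5 more models than leaf (standard error 69.9; 13111 ± 132.5 against 12300 ± 44.8, SD, n = 4 each, exact permutation test, two-sided, p = 0.0286), compared with 1268 more at a threshold set in reads. This argues against the abundant leaf models as the whole source of the difference, while leaving a part to them. A wider mix of cell types or a broader expression programme in root stays open and was not tested.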

How the results depend on the processing

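The alternatives with pseudocounts, quantile normalization, array weights, an untrended variance and the block were chosen after seeing the data. So were the abundance quartiles by mean normalized count, which replaced a ranking by mean log2 value whose outcome had been seen. Each main result was checked under several alternatives, and 124 of these checks stayed within the limits set for a like value while 11 moved. The limits were wide: 8525 calls with column totals and 5217 at adjusted p under 0.01 both passed as like 7063. Some checks could not have moved, such as the demand for 0 described below and the exact tests with a library left out, where the tissues did not overlap. The 124 are therefore no measure of robustness. No single count or difference reversed, but 3 of 4 balances of directions examined, picked after seeing the data, turned: that of all calls with quantile normalization (3958 in leaf, 3544 in root), that of the highest abundance quartile with column totals (160 and 296), and that of the root list of 100 with both. Scaling to column totals gave 1822 models higher in leaf and 6703 higher in root, and 5545 of the 7063 models called were called under it too. The test against 4-fold left 1169 models. A limit of 0.5 CPM in the other tissue gave 110 leaf-restricted and 566 root-restricted models, and a minimum of 5 CPM gave 28 and 90. The ratio of leaf to root replicate spread was 1.27 after quantile normalization, and 1.17 to 1.84 with single libraries left out, lowest without leaf library 1 and highest without root library 1. The count of models differing was 6288 to 7462 with single libraries left out and 5217 at adjusted p under 0.01. It was 7502 with quantile normalization, 8042 with array weights and 8525 with column totals. Whether most tested models differ thus depends on these choices. The table's column numbers as a replicate block gave 6574 calls, 6435 of them shared with the unblocked fit. Of the 8 libraries, 0 correlated best with the library of its own number, which cannot show whether samples were paired. The numbers are not taken as pairs because equal numbers need not mark the same flask. Calls of the 4 named models held in every alternative run on them. These models were picked as the largest differences and are at 0 throughout the other tissue, so this outcome was to be foreseen and shows no robustness. A demand for 0 in every library of the other tissue cannot change the restricted models, which are already at 0. Not run were the count-model tests and voom, thinning of reads and the gene list tests, for which the table lacks read counts or gene names, and a block on the label numbers, which the leaf columns do not carry. Depth limits the models near the worth of a single read, whose 0 does not show absence.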

Other observations

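The correlation between neighbouring model numbers was first noticed in these data and the permutation test was chosen after that; the rank correlation was set as a test before its value was seen.

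Models with neighbouring numbers tended to share their organ difference. Across 9846 pairs of tested models 1 number apart, the log2 leaf minus root differences correlated with Pearson's r = 0.147 and Spearman's rho = 0.115. The highest rho among 1000 shuffled orders was 0.031 (permutation p = 0.001, the smallest these permutations can give). The relation fell with distance, to rho = 0.054 at 2 numbers apart, 0.034 at 3 and 0.003 at 10 (permutation p = 0.39). Over the 8 distances examined the Benjamini-Hochberg adjusted p was 0.0027 at 1, 2 and 3 numbers apart and 0.52 at 10. Root-restricted models were also next to each other more often: 14 adjacent pairs among 194 models, against a mean of 2.06 and a highest value of 8 in 1000 random draws from the 13514 models with at least 1 CPM in every root library (permutation p = 0.001). The 54 leaf-restricted models gave 1 adjacent pair against a mean of 0.18 (permutation p = 0.17). A few pairs with very large differences are argued against as the source by the rank correlation of 0.115, and a chance order of models by its permutation p of 0.001. If the numbers follow the order of genes along the genome, which no source used here states, a candidate explanation is clusters of duplicated or jointly regulated genes. Gene models split in 2 and reads shared between near-identical copies would give the same pattern and stay open, because no sequence or position of a model was used here.

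Leaf libraries 1 and 4 differed in many models, and across all tested models this difference was little related to that between leaf and root. Of the 13688 tested models, 1763 were over 2-fold higher in leaf library 1 and 1517 over 2-fold higher in leaf library 4. The leaf library 1 minus leaf library 4 difference correlated across models with the organ difference taken from leaf libraries 2 and 3 and all root libraries at r = 0.021. The models with a leaf estimate over 2-fold higher in the same held-out difference were nonetheless shifted towards leaf library 1, with a median leaf library 1 minus leaf library 4 difference of 0.332 on the log2 scale, against 0.040 for those over 2-fold higher in root and 0.063 for all tested models. These medians were added after seeing that models over 2-fold higher in leaf by the main test, which uses leaf libraries 1 and 4, had a median of 0.394 and those higher in root 0. Among libraries of different tissue, the deviations of leaf library 4 and root library 2 from their tissue means had the highest correlation, 0.29, and those of leaf library 1 and root library 2 the lowest, -0.21.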
